A study of Mus musculus with 18 samples.

How the data were processed

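The deposited values are log2 expression levels for 15544 Ensembl mouse genes, with 1 set of values for each of 18 libraries. Per the submitters' processing notes, reads were aligned with STAR to the mm9 mouse genome and limma was used downstream. The read counter, the gene annotation, any filter on low genes, the strand setting and the version of each program are not given in the sources used here. The values run from 1 to 18.73, are not whole numbers, and have nearly the same distribution in every library: within the top 90% of ranks no library departs from another by more than 0.0319 log2 units at the same rank. This shows quantile normalization over the 18 libraries by the authors before deposit. Library totals cannot be recovered from such values, so the depth behind each level is unknown, and no interval for counting error is given. Quantile normalization also gives every library the same median, so a change shared by most genes would not be visible and every change is relative to the other genes of that library. Because the values were already on the log2 scale, no pseudocount was added.

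Gene symbols, chromosomes and the order of genes along a chromosome were taken from GENCODE vM21 on GRCm38 by Ensembl identifier. The authors aligned to mm9, an older build, so only names and order are used and no coordinates are given. Of the 15544 identifiers, 14994 had a symbol there and 550 had none and cannot be named. Levels of genes from families with near-identical members, here H2-Q1, Trim12a, Gvin1, Kng2, Hba-a1, Hbb-bs, Skint3 and Raet1e, can include reads shared with other members, and levels of transcripts that overlap a gene on the other strand can include its reads.

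Genes with a mean below 6 log2 units over the 18 libraries were left out, which removed 295 genes and left 15249 for testing. A linear model with 1 mean per genotype was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend (14 residual and 17.0 total degrees of freedom). The 6 comparisons between genotypes were contrasts of this model, each tested on both sides and adjusted by Benjamini-Hochberg over the genes tested, and a gene counts as changed below an adjusted p of 0.05. A change is the difference of mean log2 levels, first-named genotype minus second, and its SE comes from the model. Levels are given with the SD over libraries. For single genes an exact permutation test of the difference of means was also run. There are 252 regroupings of 5 against 5 libraries, 126 of 5 against 4 and 70 of 4 against 4, and the smallest 2-sided exact p these can give is 0.00794, 0.00794 and 0.0286. Self-test data with the real spread and 200 changed genes gave back 41.8% to 47.8% of genes shifted by 0.5 log2 units, 73.1% to 85.1% of those shifted by 1 and 95.5% to 100% of those shifted by 2.

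Gene lists, 32 in all, were fixed in advance: markers of alveolar type 1 and type 2, club, ciliated, mucous, basal and neuroendocrine cells; epithelial junctions; lung transcription factors; type 2 inflammation; NF-kB targets and cytokines; interferon response; MHC class II; immediate early and heat shock genes, which tissue dissociation can induce; cell cycle; surfactant lipid synthesis; xenobiotic metabolism; Notch; Wnt; TGF-beta and mesenchymal transition; oxidative phosphorylation; ribosomal proteins; unfolded protein response; macrophages; lymphocytes; granulocytes; endothelium; mesenchyme; red cells and platelets; cardiac muscle; sex; and the Foxa2 locus. They were tested with camera, which asks whether the genes of a list moved more in one direction than the other genes, with a preset correlation of 0.01 between genes and adjustment over the 32 lists of a comparison. The same test was run with a correlation estimated from each list. The fry test, which asks only whether a list's genes moved on balance one way and does not compare them with other genes, was run as an alternative. Counts of list members are given after adjustment over all genes and, in those words, adjusted over the list alone. Several lists share genes: 7 of the 22 measured club genes, 6 of the 22 TGF-beta and mesenchymal transition genes and 4 of the 25 mesenchymal genes stand in another list, and 0 of the 24 endothelial genes do.

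The lists, the tests, the filter, the alternatives other than those named as added later, and the rule for naming genes were chosen before the data were examined. Foxa2 and the Falcor transcript are given in every comparison with wild type. Beyond these, each comparison with wild type names the 6 largest rises and the 6 largest falls among changed genes whose mutant libraries all lie on the same side of the wild-type mean, leaving out predicted genes, pseudogenes, immunoglobulin and T cell receptor segments and sex genes. For the 6 lists other than sex with the smallest camera p it names up to 3 changed members with the smallest p, or 2 with the smallest p where none changed. Comparisons between mutant genotypes name the 5 largest rises and falls by the same rule. Every other gene named, including members given where a list count is 5 or fewer and the neighbours of Foxa2 with their separate values, was chosen after the values were seen. A few single-gene results that these rules would name are not reported here.

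Fold changes against wild type share the wild-type libraries, which alone makes them correlate. Each correlation between them is therefore set beside the value from 1000 simulations of unchanged groups that share their controls and beside the mean over splits of the 5 wild-type libraries, 10 ways of choosing 2, in which each comparison had its own controls. The labels give no batch, litter, day of collection or sex, and do not say whether each library came from a separate animal or from pooled cells. The p-values therefore measure the spread between these samples. The labels also do not state which part of the Falcor gene was removed.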

Results

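RNA of lung epithelial cells was sequenced from mice 10 to 12 weeks old, after cells carrying the epithelial surface protein EpCAM had been captured on magnetic beads. Total RNA was used. The 18 libraries fall into 4 genotypes: wild type (n = 5, replicates 1 to 5), Falcor-/- (n = 5, replicates 6 to 10), Foxa2+/- (n = 4, replicates 11 to 14), and animals labelled double-heterozygous, Falcor+/-;Foxa2+/- (n = 4, replicates 15 to 18). Foxa2 encodes a forkhead transcription factor of the lung and other endoderm-derived epithelia. Falcor is a long non-coding RNA transcribed from the neighbouring gene, annotated as 9030622O22Rik (ENSMUSG00000086141). The comparisons here ask how the epithelial transcriptome differs when Falcor, a copy of Foxa2, or a copy of each is removed. Log2 levels of 15249 genes were tested, and the depth of each library is unknown. Pearson's r between libraries, across genes, was 0.964 to 0.984 within a genotype and 0.937 to 0.975 between genotypes. Ddx3y, a Y-linked gene, lay between 12.61 and 13.07 in the 18 libraries, and Xist, the RNA that silences an X chromosome in females, between 5.38 and 7.63.

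Falcor RNA was nearly lost in Falcor-/- cells and was higher, not lower, in both groups labelled heterozygous for Foxa2. Its level was 10.18 ± 0.48 (SD, n = 5) in wild type and 6.20 ± 0.68 (SD, n = 5) in Falcor-/-, or 6.36% of wild type (change -3.98, SE 0.27, adjusted p = 6.35e-07). In Foxa2+/- libraries the level was 11.70 ± 0.21 (SD, n = 4), 2.86 times wild type (adjusted p = 0.00325). In the libraries labelled double-heterozygous it was 11.66 ± 0.15 (SD, n = 4), 2.78 times wild type (adjusted p = 0.00242). The exact permutation p was 0.00794 in each of these 3 comparisons, the smallest that groups of these sizes can give. The double-heterozygous label includes loss of a Falcor copy, yet Falcor RNA in those libraries differed from Foxa2+/- by only -0.04 (95% confidence interval -0.68 to 0.60, adjusted p = 0.954). That interval excludes a fall of 1 log2 unit. The removed copy therefore does not show in this transcript's level, and the group is called by its label throughout.

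Foxa2 (ENSMUSG00000037025) was 12.97 ± 0.08 (SD, n = 5) in wild type and fell in both genotypes lacking a Foxa2 copy. It was 12.39 ± 0.05 (SD, n = 4) in Foxa2+/-, or 67.3% of wild type (change -0.57, SE 0.10, adjusted p = 0.00245). It was 12.36 ± 0.19 (SD, n = 4) in the libraries labelled double-heterozygous, or 65.8% of wild type (change -0.60, SE 0.10, adjusted p = 0.000891). The exact permutation p was 0.00794 for both. In Falcor-/- cells Foxa2 was 12.74 ± 0.23 (SD, n = 5), 85.2% of wild type and lower in 4 of 5 libraries. This did not pass (change -0.23, SE 0.10, 95% confidence interval -0.44 to -0.02, adjusted p = 0.115, exact permutation p = 0.0794). With library weights, an alternative setting, it did (change -0.27, adjusted p = 0.0485), and without Falcor-/- replicate 10 the change was -0.15. Foxa2 was 0.34 (SE 0.10) higher in Falcor-/- than in Foxa2+/- (adjusted p = 0.0353). Between the libraries labelled double-heterozygous and Foxa2+/- its difference was -0.03 (95% confidence interval -0.26 to 0.20, adjusted p = 0.901).

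With the mean of the endothelial list as a covariate, the calls of Foxa2 and Falcor in Foxa2+/- and in the double-heterozygous label were lost. The estimates then were -0.96 and -1.09 for Foxa2 (adjusted p = 0.147 and 0.087) and 2.09 and 2.18 for Falcor (adjusted p = 0.908 and 0.645). The unadjusted limma p was 1.93e-05 and 2.85e-05 for Foxa2 and 0.00102 and 0.00252 for Falcor, so the calls were lost in the adjustment over all genes. Of the covariate's variance 82.3% lies between genotypes, and the SE grew from 0.104 to 0.162 and 0.189 for Foxa2 and from 0.287 to 0.522 and 0.609 for Falcor.

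**Figure D1:**
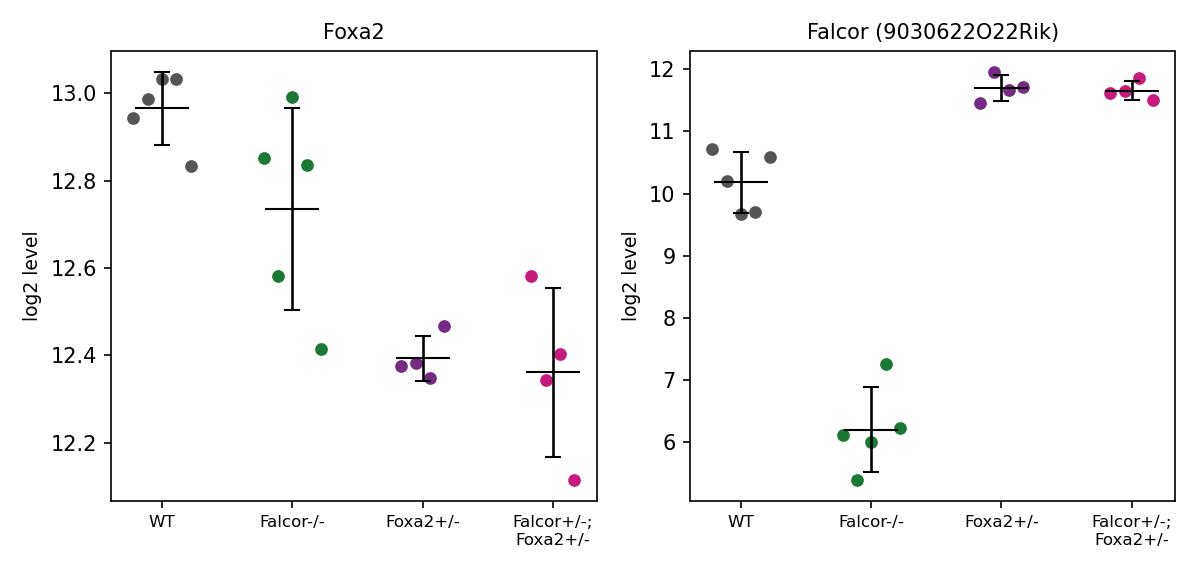
Log2 expression level (vertical axes) of Foxa2 and of Falcor in each of the 18 libraries by genotype (horizontal axis), each point a library, with bars giving the mean and SD. Falcor libraries lie at 5.39 to 7.27 in Falcor-/- against 9.68 to 10.72 in wild type and 11.46 to 11.96 in Foxa2+/-, and Foxa2 means run from 12.97 in wild type to 12.36 in the libraries labelled double-heterozygous.

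Both genes lie on the minus strand of chromosome 2. Of the other 6 tested genes of the locus, the endothelial genes Thbd, which encodes thrombomodulin, and Cd93 had the largest differences. Thbd fell to 43.8% of wild type in Falcor-/-, 24.6% in Foxa2+/- and 12.5% in the double-heterozygous label (adjusted p = 0.0285, 0.000947 and 3.69e-05). Cd93 changed by -1.80 in Foxa2+/- and -3.16 in the double-heterozygous label (adjusted p = 0.0181 and 0.00014). Its change of -1.29 in Falcor-/- did not pass (adjusted p = 0.0534). Xrn2, an RNA exonuclease gene, rose by 0.20 in Falcor-/- and 0.21 in Foxa2+/- (adjusted p = 0.0404 and 0.0483), with 0.12 in the double-heterozygous label (adjusted p = 0.217). Nxt1, Gzf1 and Napb did not pass against wild type. The mean of the 24 endothelial markers, genes of another cell type, was 12.35 ± 0.52 (SD, n = 5) in wild type. It was 11.59 ± 0.68 (SD, n = 5) in Falcor-/-, 10.46 ± 0.18 (SD, n = 4) in Foxa2+/- and 10.03 ± 0.26 (SD, n = 4) in the double-heterozygous label. No difference passed adjusted over the list means (exact permutation p = 0.119, 0.0159 and 0.00794, adjusted p = 0.195, 0.0714 and 0.0714).

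**Figure D2:**
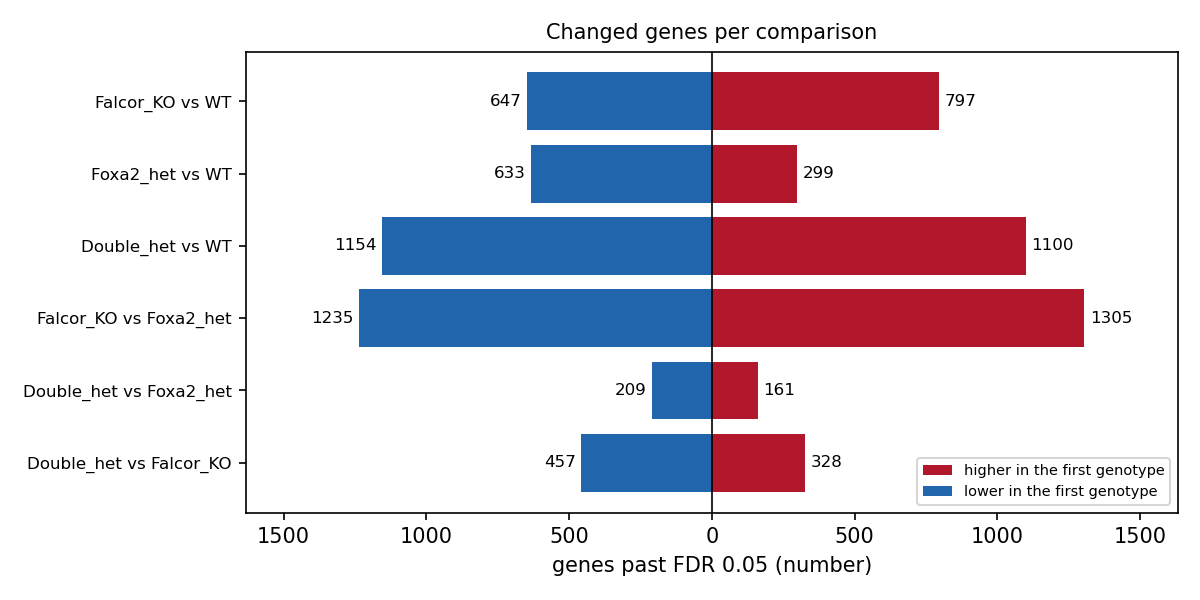
Number of genes past a false discovery rate of 0.05 (horizontal axis) in each of the 6 comparisons between genotypes (vertical axis), with bars to the right for genes higher and to the left for genes lower in the first-named genotype. The largest total is 2540 genes for Falcor-/- against Foxa2+/- and the smallest is 370 for the double-heterozygous label against Foxa2+/-.

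The comparison of Falcor-/- with wild type asks what loss of Falcor changes. Aass, which encodes an enzyme of lysine breakdown, rose from 10.91 ± 0.66 (SD, n = 5) to 14.16 ± 0.37 (SD, n = 5), by 3.25 (SE 0.49, adjusted p = 0.00182). Cst8, a cystatin family gene, rose by 3.42 (SE 0.58, adjusted p = 0.00482) and Camk2b, which encodes a calcium-dependent kinase subunit, by 3.79 (SE 1.02, adjusted p = 0.033). AA467197 rose by 3.44 (SE 0.82, adjusted p = 0.0233), Trim66 by 2.85 (SE 0.80, adjusted p = 0.0384) and the kininogen gene Kng2 by 2.45 (SE 0.66, adjusted p = 0.0337). The falls were led by the serine protease gene Prss22 (-4.37, SE 1.05, adjusted p = 0.0234), the MHC class I-like gene H2-Q1 (-4.05, SE 0.81, adjusted p = 0.0119) and F13a1, which encodes the A subunit of coagulation factor XIII (-3.97, SE 0.86, adjusted p = 0.0151). The collagenase gene Mmp13 (-3.81, SE 0.83, adjusted p = 0.0154), the secreted phospholipase gene Pla2g2d (-2.92, SE 0.76, adjusted p = 0.0296) and the lectin gene Cd209f (-2.87, SE 0.80, adjusted p = 0.0367) followed. Several of these differences came from some libraries only. Trim66 and AA467197 were low in wild-type replicates 1, 2 and 5 (3.08, 3.26 and 2.22, and 2.20, 3.79 and 4.92), while replicates 3 and 4 (7.14 and 7.13, and 7.71 and 8.19) lay near the Falcor-/- means of 7.42 ± 0.30 and 8.80 ± 0.53 (SD, n = 5). Camk2b was 9.89 in wild-type replicate 4, near the 9.33 to 10.48 of Falcor-/-. F13a1 was 4.81, 5.91 and 7.52 and Cd209f 2.59, 4.61 and 4.88 in Falcor-/- replicates 6, 8 and 10, against 10.87 and 10.39, and 7.74 and 7.85, in replicates 7 and 9. Of the 10 runs that each left out 1 library of these genotypes, the call was lost in 7 for Camk2b, Trim66 and Cd209f, 5 for Kng2, 4 for Pla2g2d and 3 for AA467197 and Prss22.

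Ribosomal protein genes rose together in Falcor-/- cells, 21 of 40, or 35 adjusted over the list alone. Rps24 rose by 0.73 (SE 0.12) and Rpl4 by 0.32 (SE 0.07), and the list median was 0.33 (adjusted p = 5.97e-12, and adjusted p = 0.699 with an estimated correlation). Oxidative phosphorylation genes rose in 5 of 38 cases, or 23 adjusted over the list alone: the ATP synthase genes Atp5c1 and Atp5o by 0.31 and 0.40, Sdhc of complex II by 0.24, and Cox6c and Cox4i1 of complex IV by 0.41 and 0.37. The median was 0.30 (adjusted p = 4.53e-07, and adjusted p = 0.699 with an estimated correlation). Among MHC class II genes H2-Oa, H2-Ob and H2-DMa, which belong to the peptide-loading machinery, rose by 0.98, 0.71 and 0.54, 3 of 12, also adjusted over the list alone. That list had a median of 0.41 (adjusted p = 0.0122, and adjusted p = 0.699 with an estimated correlation). Ier2 and Jund rose by 0.41 and 0.31, 2 of 29 immediate early and heat shock genes, or 0 adjusted over the list alone. The median was 0.28 (adjusted p = 0.0022, and adjusted p = 0.699 with an estimated correlation). Ciliated cell genes rose in 3 of 40 cases, also adjusted over the list alone: AU040972 by 1.19, Ccno, which drives centriole amplification, by 0.72 and the dynein gene Dnaic1 by 0.65. Their median was 0.25 (adjusted p = 0.0216, and adjusted p = 0.863 with an estimated correlation). Leaving out 1 library ended the call of Atp5o, Sdhc, Ier2 and Jund in 8 of 10 runs each, of Atp5c1 in 5, of H2-Ob and the ciliated list in 3, of Rpl4 in 2 and of H2-DMa in 1.

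Of 25 mesenchymal genes 5 fell, also adjusted over the list alone: the elastin gene Eln (-1.69, SE 0.33), Pdgfra (-1.34), the collagen VI genes Col6a2 (-1.23, SE 0.23) and Col6a1 (-1.13, SE 0.25), and Npnt (-0.60). The median was -0.73 (adjusted p = 1.74e-05, and adjusted p = 0.699 with an estimated correlation). All 24 endothelial genes lay below wild type, and Lyve1, a lymphatic marker, was the only 1 that fell, also adjusted over the list alone (-2.24, SE 0.47). The endothelial median was -0.79 (adjusted p = 4.91e-06, and adjusted p = 0.699 with an estimated correlation). Replicate 10 stood apart, with an endothelial mean of 12.66 and a mesenchymal mean of 10.93 against 12.35 and 11.02 in wild type, and the other Falcor-/- libraries had endothelial means of 10.86 to 11.67. Zeb2 (-1.09) was the only 1 of 22 TGF-beta and mesenchymal transition genes to fall, also adjusted over the list alone. Its list had a median of -0.19 (adjusted p = 0.0356, and adjusted p = 0.699 with an estimated correlation). The basal and mucous lists had medians of -0.61 and -0.44 (adjusted p = 0.0171 for each, and adjusted p = 0.699 with an estimated correlation), with 0 of 12 and 0 of 19 genes passing in limma, also adjusted over the list alone.

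Interferon genes went both ways. Tap1 and Psmb8 of the antigen-processing machinery rose by 0.69 and 0.49 and Oas2 (-1.79), Gbp3 (-0.73) and Ddx58 (-0.36) fell, 2 higher and 3 lower of 31, or 2 and 6 adjusted over the list alone. The interferon list was lower as a whole (adjusted p = 0.0215, and adjusted p = 0.737 with an estimated correlation). So was the locus list, with 1 higher and 2 lower of 8, or 1 and 5 adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.418 with an estimated correlation). Without 1 library, the call was lost for the interferon and TGF-beta lists in 4 of 10 runs each, for the mucous list in 2, and for the basal list and Col6a1 in 1.

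The other 20 lists did not pass in this comparison. Of the epithelial identities, adjusted p was 0.0612 for alveolar type 1, 0.867 for alveolar type 2, 0.588 for club, 0.241 for neuroendocrine cells, 0.251 for junctions and 0.615 for lung transcription factors. In the Notch list (adjusted p = 0.107) Rbpj, the DNA-binding factor of the pathway (-0.82, adjusted p = 0.000209), and Notch1 (-0.64) fell, and Hes1 and Hes6 rose by 0.57 and 0.58. For the remaining states adjusted p was 0.080 for cell cycle, 0.257 for Wnt, 0.423 for xenobiotic metabolism, 0.588 for surfactant lipids and for the unfolded protein response, 0.617 for type 2 inflammation, 0.766 for NF-kB and 0.669 for sex. For other cell types it was 0.257 for macrophages, 0.669 for lymphocytes, 0.617 for granulocytes, 0.588 for red cells and platelets and 0.533 for cardiac muscle. Of the macrophage genes 6 of 22 fell, also adjusted over the list alone: the complement genes C1qc (-2.96), C1qb (-2.63) and C1qa (-2.42), the scavenger receptor gene Msr1 (-2.67), Csf1r (-1.05) and Adgre1 (-0.95). Falcor-/- replicates 6, 8 and 10 carried the fall, as for F13a1 and Cd209f. C1qc was 7.94, 8.45 and 8.73 there and 12.56 and 13.29 in replicates 7 and 9, against 12.79 to 13.53 in wild type. The median of that list was 0.08 and its mean -0.41, and the red cell and platelet list had a median of 0.04 and a mean of -0.29. The NF-kB and alveolar type 2 lists, tested as lower, had medians of -0.01 and -0.02 and means of 0.01 each.

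In all, limma called 1444 of 15249 genes changed in Falcor-/- against wild type, 797 higher and 647 lower, with 286 changed by at least 1 log2 unit. The number depended on single libraries: it was 354 without wild-type replicate 1, 422 without replicate 2 and 665 without replicate 4. It was 703 without Falcor-/- replicate 6, 3926 without replicate 7 (1432 of them shared with the 1444), 472 without replicate 8 and 523 without replicate 9. It was 483 in a fit of these genotypes alone, 3446 with library weights, 414 with Xist as a covariate and 157 with the endothelial mean as a covariate, of which 151 were among the 1444. The number of lists passing moved from 12 to between 7, without wild-type replicate 5, and 15, without wild-type replicate 3.

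The comparison of Foxa2+/- with wild type asks what loss of a Foxa2 copy changes. Kng2 rose from 4.24 ± 0.89 (SD, n = 5) to 8.13 ± 1.40 (SD, n = 4), by 3.89 (SE 0.70, adjusted p = 0.00234). Cst8 rose by 3.25 (SE 0.61, adjusted p = 0.00311), Svopl by 2.22 (SE 0.42, adjusted p = 0.00311) and the lens filament gene Bfsp1 by 2.15 (SE 0.25, adjusted p = 0.000595). Nipal4 rose by 2.29 (SE 0.61, adjusted p = 0.0326) and the receptor tyrosine kinase gene Ros1 by 2.10 (SE 0.48, adjusted p = 0.0141). Col13a1, a transmembrane collagen gene, fell furthest (-3.08, SE 0.43, adjusted p = 0.000667). Cyp26b1, which encodes a retinoic acid-degrading enzyme (-3.01, SE 0.84, adjusted p = 0.0401), the adenylate cyclase gene Adcy8 (-3.01, SE 0.48, adjusted p = 0.000995) and Dach1 (-3.01, SE 0.37, adjusted p = 0.000595) were next. Ccn5 (-2.86, SE 0.51, adjusted p = 0.00211) and the fibroblast growth factor receptor gene Fgfr4 (-2.84, SE 0.40, adjusted p = 0.000667) also fell. Leaving out 1 library ended the call of Nipal4 and Cyp26b1 in 6 of 9 runs each and of Ros1 in 1.

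Of all lists the endothelial markers had the lowest median in Foxa2+/-, and 20 of 24 fell, or 22 adjusted over the list alone. Cldn5 of endothelial tight junctions went from 13.48 ± 0.73 (SD, n = 5) to 11.01 ± 0.34 (SD, n = 4), Cdh5, VE-cadherin, from 14.35 ± 0.59 (SD, n = 5) to 11.96 ± 0.24 (SD, n = 4), and the transcription factor gene Erg changed by -2.11 (SE 0.32). The list median was -2.15 (adjusted p = 1.15e-28, and adjusted p = 0.122 with an estimated correlation). Mesenchymal genes fell in 11 of 25 cases, also adjusted over the list alone, among them Mfap4 (-2.70), Pdgfra (-2.48) and the methyltransferase gene Inmt (-2.36). Their median was -0.93 (adjusted p = 4.34e-11, and adjusted p = 0.167 with an estimated correlation). Replicate 14 stood apart with a list mean of 11.16, above the wild-type mean of 11.02, against 9.23 to 10.27 in the other Foxa2+/- libraries. The list mean itself did not pass (exact permutation p = 0.0794, and 0.168 adjusted over the list means). The matrix genes Tnc (-1.81), Ccn2 (-1.04) and Sparc (-0.81) and Tagln of smooth muscle (-0.93) fell, 4 of 22 TGF-beta and mesenchymal transition genes, or 7 adjusted over the list alone. That list was lower (adjusted p = 1.32e-05, and adjusted p = 0.181 with an estimated correlation). Notch genes fell in 7 of 20 cases, or 1 higher and 9 lower adjusted over the list alone, among them Dll4 (-1.90), Hey1 (-1.45) and Notch4 (-0.78), genes with known roles in vessels. The Notch list was lower (adjusted p = 0.00081, and adjusted p = 0.122 with an estimated correlation). The Wnt genes Nkd2 (-1.98), Lef1 (-1.80), Tnfrsf19 (-1.33), Wif1 (-1.18) and Tcf7 (-1.12) fell, 5 of 22, or 6 adjusted over the list alone (adjusted p = 0.0257, and adjusted p = 0.312 with an estimated correlation). The call of Sparc was lost in 2 of 9 runs without a library.

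Among epithelial groups, alveolar type 1 markers fell in 10 of 21 cases, or 14 adjusted over the list alone: Rtkn2 (-1.27, SE 0.23), the chloride channel gene Clic5 (-1.16, SE 0.21), Sema3e (-0.87, SE 0.13) and Hopx, a homeobox gene of these cells (-0.77), were among them. The median was -0.59 (adjusted p = 1.9e-11, and adjusted p = 0.167 with an estimated correlation). The endothelial mean moved along in the same libraries, at 10.46 ± 0.18 (SD, n = 4) against 12.35 ± 0.52 (SD, n = 5). With it as a covariate the type 1 list turned to higher without passing (adjusted p = 0.486). Ciliated genes lay lower in 38 of 40 cases with a median of -0.34 (adjusted p = 1.04e-09, and adjusted p = 0.401 with an estimated correlation). Of these only Iqcg fell, also adjusted over the list alone (-0.56, SE 0.12). Alveolar type 2 genes lay slightly higher, with a median of 0.13 (adjusted p = 0.025, and adjusted p = 0.771 with an estimated correlation), and Mlc1 alone of 24 rose, also adjusted over the list alone, by 0.58.

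NF-kB targets and cytokines rose in 6 of 25 cases in Foxa2+/-, or 7 higher and 1 lower adjusted over the list alone. The serum amyloid gene Saa3 rose by 1.55 (SE 0.41), Il6 by 1.48, the neutrophil chemokine gene Cxcl1 by 1.41 (SE 0.25), Nfkbiz by 0.66, Lcn2 by 0.65 and Birc3, an apoptosis inhibitor gene, by 0.43 (SE 0.08). The list median was 0.49 (adjusted p = 2.52e-05, and adjusted p = 0.167 with an estimated correlation). The call of Saa3 was lost in 7 of 9 runs without a library. Immediate early genes lay higher with 0 of 29 passing in limma, also adjusted over the list alone (adjusted p = 0.0474, and adjusted p = 0.771 with an estimated correlation). Lymphocyte genes lay lower with 0 of 16 passing in limma, also adjusted over the list alone, and a median of -0.49 (adjusted p = 0.00287, and adjusted p = 0.383 with an estimated correlation). Among cardiac muscle genes Myh7 (-1.17) alone of 5 fell, or 2 adjusted over the list alone (adjusted p = 0.0376, and adjusted p = 0.167 with an estimated correlation).

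In all, limma called 932 genes changed in Foxa2+/- against wild type, 299 higher and 633 lower, and 468 of them by at least 1 log2 unit. The count was 606 without Foxa2+/- replicate 12, 556 without replicate 13 and 1947 with library weights. With the endothelial mean as a covariate limma called 0 genes, so every gene call of this comparison was lost, and 619 had an unadjusted p under 0.05 against 2931 before. The TGF-beta and lymphocyte lists then turned to higher without passing (adjusted p = 0.594 and 0.73). The list calls of immediate early genes were lost in 5 of 9 runs without a library, of cardiac muscle in 3 and of alveolar type 2 in 2. The other 20 lists did not pass (smallest adjusted p = 0.0843, neuroendocrine). The locus, junction, ribosomal, granulocyte and type 2 inflammation lists differed in sign between median, mean and test. Of these the locus list had a median of 0.05 and a mean of -0.31, and the granulocyte list a median of -0.01 and a mean of 0.07.

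**Figure D3:**
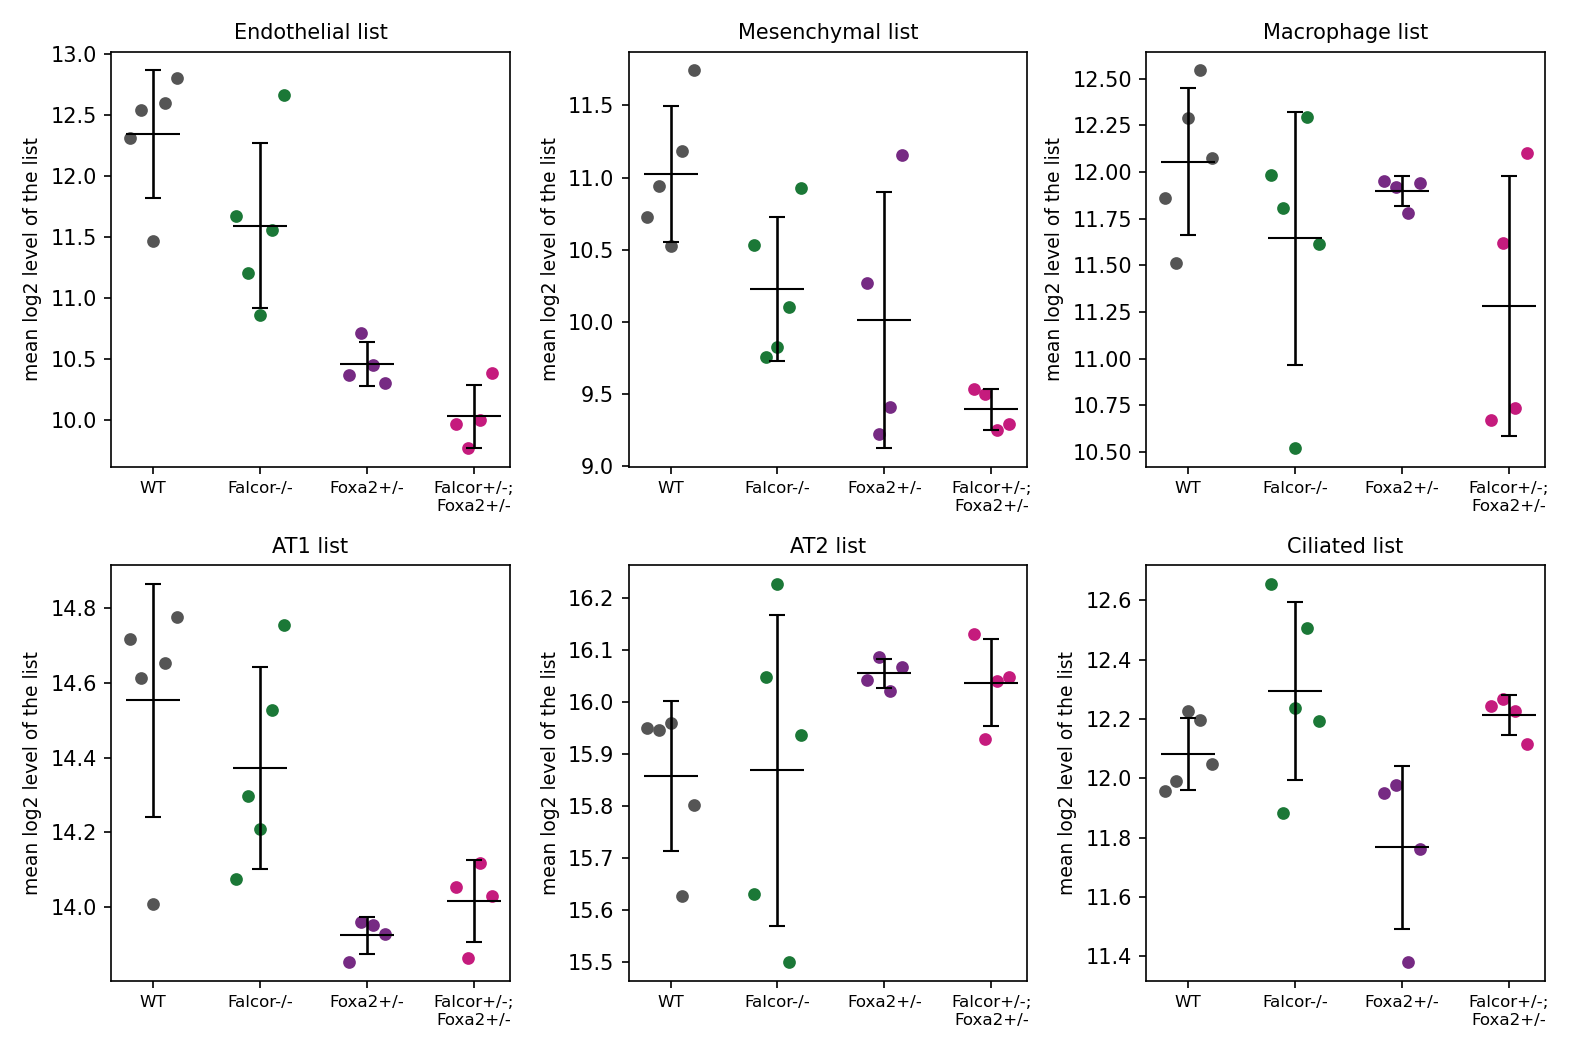
Mean log2 level (vertical axes) of the endothelial, mesenchymal, macrophage, alveolar type 1, alveolar type 2 and ciliated lists in each of the 18 libraries by genotype (horizontal axis), each point a library, with bars giving the mean and SD. The endothelial mean declines from 12.35 in wild type to 10.03 in the double-heterozygous label, and the alveolar type 1 mean is 14.55 in wild type and 13.92 in Foxa2+/-.

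The double-heterozygous libraries, whose Falcor RNA is not reduced, were compared with wild type to ask what loss of a copy of each gene changes. F13a1 fell from 11.87 ± 0.18 (SD, n = 5) to 5.81 ± 0.59 (SD, n = 4) (change -6.06, SE 0.91, adjusted p = 0.000264). Cd209f (-5.22, SE 0.84, adjusted p = 0.000518), the B cell chemokine gene Cxcl13 (-4.77, SE 0.93, adjusted p = 0.00239) and Pla2g2d (-4.71, SE 0.80, adjusted p = 0.000819) fell as well. So did Mmp13 (-4.68, SE 0.88, adjusted p = 0.00173) and H2-Q1 (-4.52, SE 0.86, adjusted p = 0.00197). Trim12a rose by 4.70 (SE 1.41, adjusted p = 0.0333, exact permutation p = 0.0635) from 5.71 ± 3.89 (SD, n = 5) in wild type. Kng2 rose by 4.32 (SE 0.70, adjusted p = 0.000544), Cst8 by 3.89 (SE 0.61, adjusted p = 0.0004) and AA467197 by 3.63 (SE 0.87, adjusted p = 0.0101). The glycoprotein gene Azgp1 rose by 3.29 (SE 1.05, adjusted p = 0.0439) and the interferon-inducible GTPase gene Gvin1 by 2.86 (SE 0.90, adjusted p = 0.0403, exact permutation p = 0.0635). Wild-type replicates 1, 2 and 5 were low in Trim12a (2.20, 2.18 and 4.51), Gvin1 (4.18, 3.26 and 2.22) and, as above, AA467197. Replicates 3 and 4 (9.85 and 9.83, and 7.26 and 7.08) lay at or near the double-heterozygous libraries (9.85 to 10.91, and 7.25 to 8.15). Of 9 runs without a library the call was lost in 6 for Trim12a and 7 for Azgp1 and Gvin1, and Azgp1 was -0.55 with the endothelial mean as a covariate.

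Endothelial, mesenchymal and matrix genes fell in the same libraries. Of 24 endothelial genes 21 fell, or all 24 adjusted over the list alone, with Cdh5 (-2.99, SE 0.36), Cldn5 (-2.93, SE 0.36) and the endothelin receptor gene Ednrb (-2.55, SE 0.32) among them. The median was -2.55 (adjusted p = 1.09e-26, and adjusted p = 0.0867 with an estimated correlation). Of 25 mesenchymal genes 18 fell, or 20 adjusted over the list alone, including Pdgfra (-2.99), Mfap4 (-2.84) and Col6a2 (-1.87). Their median was -1.67 (adjusted p = 2.92e-16, and adjusted p = 0.0867 with an estimated correlation). Of 22 TGF-beta and mesenchymal transition genes 12 fell, or 15 adjusted over the list alone, including Tnc (-2.02), the transcription factor gene Snai1 (-1.58, SE 0.18) and Tagln (-1.18). That list had a median of -0.88 (adjusted p = 2.74e-12, and adjusted p = 0.0867 with an estimated correlation). Of 20 Notch genes 2 rose and 5 fell, or 2 and 6 adjusted over the list alone, with Dll1 at -1.98 and Nrarp at 0.68 (adjusted p = 0.0053, and adjusted p = 0.132 with an estimated correlation).

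The globin genes Hbb-bs (-3.60) and Hba-a1 (-3.27) and the platelet factor gene Pf4 (-3.16) fell, 3 of 4 red cell and platelet genes, also adjusted over the list alone (adjusted p = 0.000176, and adjusted p = 0.0867 with an estimated correlation). Macrophage genes fell in 6 of 22 cases, also adjusted over the list alone, with C1qc (-4.14), C1qa (-3.59), C1qb (-3.54) and Msr1 (-3.43) lowest. The macrophage list was lower with a median of -0.22 and 9 of 22 members positive (adjusted p = 0.00942, and adjusted p = 0.688 with an estimated correlation). The gelatinase gene Mmp9 (-4.25) and Csf3r (-1.77), which encodes the receptor for granulocyte colony-stimulating factor, fell, 2 of 7 granulocyte genes, also adjusted over the list alone (adjusted p = 0.00706, and adjusted p = 0.37 with an estimated correlation). The lymphocyte list did not pass (adjusted p = 0.243).

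Alveolar type 1 markers fell in the libraries labelled double-heterozygous, with 11 lower and only Clic3 higher of 21, or 13 lower and 2 higher adjusted over the list alone. Among them were the caveolin gene Cav1 (-1.29, SE 0.23), Spock2 (-1.28, SE 0.27) and the basement membrane collagen gene Col4a3 (-1.04, SE 0.23). The median was -0.47 (adjusted p = 4.23e-06, and adjusted p = 0.385 with an estimated correlation). The endothelial mean in the same libraries was 10.03 ± 0.26 (SD, n = 4), and with it as a covariate the list turned to higher (adjusted p = 0.000667), with Cav1 at 0.09 and Spock2 at 0.32. The paraoxonase gene Pon1 rose by 0.85, the glutathione transferase gene Gsta3 by 0.82 and the secretoglobin gene Scgb3a2 by 0.67, 3 of 22 club cell genes, also adjusted over the list alone (adjusted p = 0.00474, and adjusted p = 0.688 with an estimated correlation). Xenobiotic genes went 8 higher and 2 lower of 33, or 14 and 2 adjusted over the list alone, with Cyp1b1 up by 1.47, Gsta2 by 1.21 and Nqo1 by 1.07, and Cyp1a1 at -2.18. Their median was 0.40 (adjusted p = 0.00326, and adjusted p = 0.688 with an estimated correlation).

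NF-kB targets and cytokines, which rose in Foxa2+/-, fell in the double-heterozygous label in 9 of 25 cases, or 10 adjusted over the list alone. Cxcl1 (-1.34, SE 0.25), the monocyte chemokine gene Ccl2 (-0.77, SE 0.17) and the adhesion receptor gene Icam1 (-0.69, SE 0.10) were among them. The median was -0.49 (adjusted p = 0.000176, and adjusted p = 0.209 with an estimated correlation). The immediate early genes Klf2 (-0.98), Dusp2 (-0.90), Klf4 (-0.62), Dusp1 (-0.52) and Jun (-0.32) fell, 5 of 29, also adjusted over the list alone (adjusted p = 0.00349, and adjusted p = 0.688 with an estimated correlation). Of 31 interferon genes 1 rose and 5 fell, also adjusted over the list alone: Tap1 at 0.51, and Oas2 (-1.61), Cxcl10 (-1.26), Gbp3 (-0.86), Ifit2 (-0.75) and Gbp2 (-0.75). The interferon list was lower (adjusted p = 0.00706, and adjusted p = 0.688 with an estimated correlation). Rps2, Rpl3 and Rps24 rose by 0.78, 0.58 and 0.40, 3 of 40 ribosomal genes, or 2 adjusted over the list alone (adjusted p = 0.000584, and adjusted p = 0.721 with an estimated correlation). Sdhc and Sdha rose by 0.26 and 0.22, 2 of 38 oxidative phosphorylation genes, or 0 adjusted over the list alone (adjusted p = 0.00249, and adjusted p = 0.721 with an estimated correlation).

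In all, limma called 2254 genes changed in the double-heterozygous label against wild type, 1100 higher and 1154 lower, 781 of them by at least 1 log2 unit. The count was 1374 without double-heterozygous replicate 15, 1342 without replicate 16, 4939 with library weights, 994 with the mean of the immune lists as a covariate and 2 with the endothelial mean. With the latter the Notch, interferon and macrophage lists turned to higher without passing (adjusted p = 0.562, 0.923 and 0.936). The list calls of macrophages and immediate early genes were lost in 2 of 9 runs without a library and that of oxidative phosphorylation in 1. The other 17 lists did not pass (smallest adjusted p = 0.0784, basal). The type 2 inflammation list, tested as lower, had a median of 0.22 and a mean of 0.09.

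Falcor-/- and Foxa2+/- cells were compared directly to ask how loss of Falcor differs from loss of a Foxa2 copy. Camk2b was 5.86 (SE 1.08, adjusted p = 0.00498) higher in Falcor-/-, Afm, which encodes a vitamin E-binding protein, 2.75 (SE 0.80, adjusted p = 0.0297) and Aass 2.73 (SE 0.51, adjusted p = 0.0056). The urea transporter gene Slc14a1 was 2.51 (SE 0.64, adjusted p = 0.0181) higher and Colq, the collagen tail of acetylcholinesterase, 2.33 (SE 0.40, adjusted p = 0.0032). Lower were Mmp13 (-4.73, adjusted p = 0.00508), F13a1 (-4.37, adjusted p = 0.00787), H2-Q1 (-3.69, adjusted p = 0.0128), Cxcl13 (-3.36, adjusted p = 0.0251) and Prss22 (-3.33, adjusted p = 0.0497). Of 9 runs without a library, the call was lost in 7 for Prss22, 5 for Cxcl13, 4 for Afm and 2 for Slc14a1.

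Ciliated genes were higher in Falcor-/- than in Foxa2+/- in 22 of 40 cases, or 29 adjusted over the list alone, among them the master regulator Foxj1 by 0.62 and the dynein gene Dynlrb2 by 0.98. Their median was 0.59 (adjusted p = 1.46e-10, and adjusted p = 0.66 with an estimated correlation). Ribosomal genes were higher in 18 of 40 cases, or 34 adjusted over the list alone (adjusted p = 2.73e-10, and adjusted p = 0.66 with an estimated correlation). Endothelial genes were higher in 17 of 24 cases, or 19 adjusted over the list alone, with Cldn5 at 2.02 and Cdh5 at 1.46 (adjusted p = 1.3e-08, and adjusted p = 0.66 with an estimated correlation). Alveolar type 1 genes, which move with that list, were higher in 7 of 21, or 9 adjusted over the list alone (adjusted p = 0.000301, and adjusted p = 0.66 with an estimated correlation). H2-Oa, H2-DMb1, H2-Ob, H2-DMa and H2-Ab1 were higher by 0.91, 0.69, 0.53, 0.52 and 0.38, 5 of 12 MHC class II genes, or 6 adjusted over the list alone (adjusted p = 0.00438, and adjusted p = 0.66 with an estimated correlation). The T cell genes Gzma, Cd3g, Trbc2, Ccl5 and Lck were higher, 5 of 16 lymphocyte genes, or 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.66 with an estimated correlation). The neuroendocrine list was higher, with Ddc at 1.42 (adjusted p = 0.012, and adjusted p = 0.66 with an estimated correlation).

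The mucous genes Slc26a4 (-2.06), Muc5b (-1.64), Muc5ac (-1.60), Pigr (-1.40) and Foxa3 (-1.25) were lower in Falcor-/- than in Foxa2+/-, 5 of 19, also adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.681 with an estimated correlation). NF-kB genes were lower in 8 of 25 cases, or 11 adjusted over the list alone, with Cxcl5 at -3.15 and Saa3 at -2.25 (adjusted p = 0.000834, and adjusted p = 0.66 with an estimated correlation). Atp5o, Atp5c1 and Cox5b were higher, 3 of 38 oxidative phosphorylation genes, or 0 adjusted over the list alone (adjusted p = 0.000116, and adjusted p = 0.754 with an estimated correlation). Rrm2 was higher alone of 30 cell cycle genes, or 0 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.754 with an estimated correlation). The myosin genes Myh7 and Myh6 were higher, 2 of 5 cardiac muscle genes, or 3 adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.423 with an estimated correlation). The other 20 lists did not pass (smallest adjusted p = 0.0578, alveolar type 2 and lung transcription factors). The macrophage list had a median of 0.18 and a mean of -0.25, the type 2 inflammation list 0.05 and -0.01, and the locus list 0.07 and -0.54.

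In all 2540 genes differed between Falcor-/- and Foxa2+/-, 1305 higher and 1235 lower in Falcor-/-. The count was 1438, 4742, 1325 and 1310 without Falcor-/- replicates 6, 7, 9 and 10, and 1333, 764 and 1292 without Foxa2+/- replicates 12, 13 and 14. It was 1181 in a fit of these genotypes alone, 4757 with library weights and 350 with Xist as a covariate. With the endothelial mean as a covariate it was 26, and the alveolar type 1 list turned to lower without passing (adjusted p = 0.993). The cell cycle list lost its call in 2 of 9 runs without a library.

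The libraries labelled double-heterozygous were compared with Foxa2+/- to ask what a Falcor copy adds, a difference that the label states and the Falcor level does not show. NF-kB targets and cytokines were lower in 12 of 25 cases, or 18 adjusted over the list alone, with a median of -0.91 (adjusted p = 2.79e-16). This was the only list of the 6 comparisons that held when the correlation was estimated, with adjusted p = 0.0107 with an estimated correlation. The chemokine genes Cxcl5 (-2.94), Cxcl1 (-2.75) and Cxcl2 (-2.48), Saa3 (-2.86) and Tnfaip3, a feedback inhibitor gene of NF-kB (-1.20), were among the 12. F13a1 (-6.46, SE 0.96, adjusted p = 0.00251), Mmp13 (-5.59, SE 0.92, adjusted p = 0.0053) and Cd209f (-5.56, SE 0.89, adjusted p = 0.00427) were lower. Cxcl13 (-5.42, SE 0.98, adjusted p = 0.00778) and Pla2g2d (-4.55, SE 0.85, adjusted p = 0.00987) were lower too. Dbp, a clock-controlled transcription factor gene, was higher by 2.13 (SE 0.54, adjusted p = 0.047), Rims2 by 1.75 (SE 0.34, adjusted p = 0.0122) and Skint3 by 1.71 (SE 0.43, adjusted p = 0.0475). The kinase gene Stk32a was higher by 1.48 (SE 0.38, adjusted p = 0.0493) and the mitochondrial adenylate kinase gene Ak4 by 1.36 (SE 0.27, adjusted p = 0.0144). Of 8 runs without a library the call was lost in all 8 for Skint3, 7 for Stk32a, 6 for Dbp and 2 for Ak4.

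Ciliated genes lay higher in the double-heterozygous label than in Foxa2+/-, with a median of 0.46 (adjusted p = 1.28e-11, and adjusted p = 0.479 with an estimated correlation). Of 40 only Dynlrb2 and Iqcg passed, at 0.89 and 0.55, or 23 adjusted over the list alone. Immediate early genes were lower in 6 of 29 cases, or 10 adjusted over the list alone, with Dusp2 at -1.19 and Fos at -0.55 (adjusted p = 3.42e-08, and adjusted p = 0.388 with an estimated correlation). Thbs1 (-1.47), Snai1 (-1.21), Ccn1 (-1.09) and Tgfbi (-0.84) were lower, 4 of 22 TGF-beta and mesenchymal transition genes, or 1 higher and 6 lower adjusted over the list alone (adjusted p = 1.84e-05, and adjusted p = 0.349 with an estimated correlation). C1qc, C1qa, C1qb, Msr1 and Csf1r were lower, 5 of 22 macrophage genes, or 1 higher and 6 lower adjusted over the list alone. The list was tested as lower with a median of -0.02 (adjusted p = 0.038, and adjusted p = 0.769 with an estimated correlation). Col6a2 (-1.70) and Col6a1 (-1.63) were lower, 2 of 25 mesenchymal genes, also adjusted over the list alone (adjusted p = 0.000293, and adjusted p = 0.595 with an estimated correlation). Lyve1 (-2.18) was lower, 1 of 24 endothelial genes, or 2 adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.769 with an estimated correlation).

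Single members of 2 blood cell lists were lower: Pf4 (-3.37), 1 of 4 red cell and platelet genes, or 3 adjusted over the list alone (adjusted p = 0.00041, and adjusted p = 0.248 with an estimated correlation), and Mmp9, 1 of 7 granulocyte genes, or 2 adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.349 with an estimated correlation). Rps2 was higher by 0.78, 1 of 40 ribosomal genes, also adjusted over the list alone (adjusted p = 1.84e-05, and adjusted p = 0.769 with an estimated correlation). Nqo1 was higher by 0.92, 1 of 33 xenobiotic genes, or 4 adjusted over the list alone (adjusted p = 0.000705, and adjusted p = 0.769 with an estimated correlation). Sec14l3 was higher by 0.63, 1 of 22 club genes, also adjusted over the list alone (adjusted p = 0.0098, and adjusted p = 0.769 with an estimated correlation). H2-Oa was higher by 1.01, 1 of 12 MHC class II genes, also adjusted over the list alone (adjusted p = 0.00617, and adjusted p = 0.589 with an estimated correlation). Oxidative phosphorylation genes lay higher with 0 of 38 passing in limma, also adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.82 with an estimated correlation).

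The other 18 lists did not pass (smallest adjusted p = 0.076, unfolded protein response), among them the lymphocyte list, tested as higher (adjusted p = 0.188). Tested as lower, the Notch list had a median of 0.04, the mucous list 0.07, the lung transcription factor list 0.06 and the type 2 inflammation list 0.07. Of 8 runs without a library the list call was lost in 4 for macrophages, 3 for oxidative phosphorylation and club genes and 1 for MHC class II. In all 370 genes differed between the double-heterozygous label and Foxa2+/-, 161 higher and 209 lower, and 148 by at least 1 log2 unit. The count was 90 and 183 without Foxa2+/- replicates 13 and 14, 171, 152 and 130 without double-heterozygous replicates 15, 16 and 17, and 2125 with library weights.

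The libraries labelled double-heterozygous were also compared with Falcor-/-, to ask what a lost Foxa2 copy does beside a Falcor gene that is still transcribed. Falcor RNA was 5.45 (SE 0.29, adjusted p = 1.02e-08) above Falcor-/-, and Foxa2 was below it (-0.37, SE 0.10, adjusted p = 0.0464). Raet1e, a ligand gene for an activating receptor of natural killer cells, was higher by 5.15 (SE 1.31, adjusted p = 0.0296), Ooep by 2.61 (SE 0.42, adjusted p = 0.00332) and Abcc8, a potassium channel regulator gene, by 2.35 (SE 0.63, adjusted p = 0.0395). Zfhx4 was higher by 2.22 (SE 0.31, adjusted p = 0.00233) and Skint3 by 2.17 (SE 0.41, adjusted p = 0.00605). Phf24 was lower (-3.70), at 7.58 ± 0.19 (SD, n = 4) against 11.28 ± 0.39 (SD, n = 5) (adjusted p = 3.11e-07). Hbb-bs (-3.83, adjusted p = 0.00202), Hba-a1 (-3.22, adjusted p = 0.00448), the matrix protein gene Postn (-2.84, adjusted p = 0.00277) and Dach1 (-2.65, adjusted p = 0.00233) were lower too. Of 9 runs without a library the call was lost in 6 for Raet1e and Abcc8.

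Endothelial genes were lower in the double-heterozygous label than in Falcor-/- in 17 of 24 cases, or 21 adjusted over the list alone, with a median of -1.77 (adjusted p = 5.25e-21, and adjusted p = 0.165 with an estimated correlation). Immediate early genes were lower in 10 of 29, or 16 adjusted over the list alone, with Dusp2 at -1.45 (adjusted p = 2.24e-11, and adjusted p = 0.183 with an estimated correlation). TGF-beta and mesenchymal transition genes were lower in 6 of 22, or 11 adjusted over the list alone, with Snai1 at -1.70 (adjusted p = 3.92e-09, and adjusted p = 0.153 with an estimated correlation). Mesenchymal genes were lower in 8 of 25, or 11 adjusted over the list alone, with Mfap4 at -2.31 (adjusted p = 1.01e-08, and adjusted p = 0.244 with an estimated correlation). Cxcl2 (-1.56), Cxcl1 (-1.11), Nfkbia (-0.74) and Icam1 (-0.45) were lower, 4 of 25 NF-kB genes, or 6 adjusted over the list alone (adjusted p = 1.01e-05, and adjusted p = 0.165 with an estimated correlation). The mucous genes Muc5ac, Slc26a4 and Muc5b were higher by 1.67, 1.61 and 1.48, 3 of 19, or 7 higher and 2 lower adjusted over the list alone. The mucous median was 0.92 (adjusted p = 0.0012, and adjusted p = 0.405 with an estimated correlation).

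The xenobiotic genes Ces1f, Cyp1b1, Nqo1, Ugt1a6a and Aox3 were higher than in Falcor-/- by 1.60, 1.26, 1.04, 0.79 and 0.76, 5 of 33, or 11 higher and 1 lower adjusted over the list alone (adjusted p = 2.22e-06, and adjusted p = 0.404 with an estimated correlation). Chad and Aox3 were higher, 2 of 22 club genes, or 9 adjusted over the list alone (adjusted p = 2.04e-05, and adjusted p = 0.405 with an estimated correlation). Hbb-bs, Hba-a1 and Pf4 were lower, 3 of 4 red cell and platelet genes, also adjusted over the list alone (adjusted p = 2.39e-05, and adjusted p = 0.153 with an estimated correlation). Mmp9 (-1.91) was lower, 1 of 7 granulocyte genes, or 2 adjusted over the list alone (adjusted p = 0.00497, and adjusted p = 0.244 with an estimated correlation). Nectin4 was higher by 0.55, 1 of 37 junction genes, also adjusted over the list alone (adjusted p = 0.0342, and adjusted p = 0.244 with an estimated correlation). Of 27 lung transcription factor genes Sox9, Ehf, Grhl2 and Cebpa were higher by 0.70, 0.51, 0.35 and 0.28 and Foxa2 was lower, or 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.0342, and adjusted p = 0.438 with an estimated correlation). Ribosomal genes lay lower with 0 of 40 passing in limma, also adjusted over the list alone (adjusted p = 0.000109, and adjusted p = 0.671 with an estimated correlation). Alveolar type 1 genes lay lower with 0 of 21 passing in limma, or 7 adjusted over the list alone (adjusted p = 0.000374, and adjusted p = 0.438 with an estimated correlation). Neuroendocrine genes lay lower with 0 of 15 passing in limma, also adjusted over the list alone (adjusted p = 0.00923, and adjusted p = 0.404 with an estimated correlation).

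The other 17 lists of this comparison did not pass (smallest adjusted p = 0.0581, oxidative phosphorylation). The locus list, tested as lower, had a median of -0.13 and a mean of 0.23, the interferon list 0.04 and -0.04, the Wnt list 0.07 and -0.07, and the type 2 inflammation list, tested as higher, -0.15 and 0.09. In all 785 genes differed, 328 higher and 457 lower in the double-heterozygous label. The count was 1233 and 425 without Falcor-/- replicates 7 and 10, 412 without double-heterozygous replicate 17, 342 in a fit of these genotypes alone and 247 with the immune covariate. With the endothelial mean as a covariate it was 4, and the alveolar type 1 list turned to higher (adjusted p = 0.000389) and the lung transcription factor list to lower without passing (adjusted p = 0.489). The junction list lost its call in 4 of 9 runs without a library and the lung transcription factor list in 3.

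The 3 sets of changes against wild type overlapped. Lower in all 3 genotypes were 109 genes, among them the matrix genes Eln, Fbn1 and Lox and the cytochrome gene Cyp1a1. In Falcor-/-, Foxa2+/- and the double-heterozygous label, Eln changed by -1.69, -1.63 and -2.40, and Cyp1a1 by -2.06, -2.08 and -2.18. Higher in all 3 were 45 genes, among them Cst8, Kng2, Bfsp1 and Ros1. Foxa2+/- and the double-heterozygous label shared 161 higher and 515 lower genes, and 5 went opposite ways. Independent calls, which ignore that the wild-type libraries are shared, would give 21.6 and 47.9, and 60 simulated pairs of unchanged groups with shared controls gave 0.0167 shared calls on average and at most 1. Falcor-/- and the double-heterozygous label shared 309 higher and 296 lower (57.5 and 49.0 for independent calls, 2 opposite), against a simulated mean of 0.167 and at most 10. Falcor-/- and Foxa2+/- shared 54 and 114 (15.6 and 26.9 for independent calls, 6 opposite), against a simulated mean of 22.7, which comes from 1 of the 60 pairs with 1360 shared calls and 0 in the others. Across 15249 genes, which are not independent replicates, Pearson's r between the changes was 0.658, 0.676 and 0.321 in that order.

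Because these comparisons share the wild-type libraries, unchanged groups gave a simulated r of 0.439 (95% of simulations 0.105 to 0.706), 0.461 (0.131 to 0.713) and 0.468 (0.152 to 0.714), and each observed r lies inside its range. With the wild-type libraries split between the comparisons r was 0.513, 0.529 and 0.178. The covariance of the changes was 0.175, 0.180 and 0.0657 against simulated 0.0291, 0.0286 and 0.029, and above the simulated 95% range, which ended at 0.0597, 0.0554 and 0.0548. The endothelial mean lay lower in all 3 genotypes, so the excess over the simulated covariance is given as a value only.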

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

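The tests of a lower epithelial share in wild type and of a larger epithelial share behind the Falcor rise were chosen only after results were seen. Each group of 4 or 5 libraries was checked, for each named gene and list mean, for a lowest or highest library that lay far from the others relative to the range of the group. Of 251 groups 16 held such a library, or 6.37%, and chance alone gives about 1 in 20.

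In 8 of the 16 that library was wild-type replicate 3, each time the lowest. Its levels were 13.31 for Cdh5, an endothelial cadherin gene (14.46 to 14.79 in the other wild-type libraries), 15.50 for the matrix gene Sparc (16.28 to 16.56) and 8.97 for Dach1 (10.06 to 10.38). Among alveolar type 1 markers they were 12.53 for Rtkn2 (13.47 to 13.73), 14.60 for Clic5 (15.38 to 15.50), 14.05 for Cav1 (14.90 to 15.25) and 13.34 for Spock2 (14.42 to 14.72). The mean of the alveolar type 1 list was 14.01 in this library and 14.61 to 14.78 in the others. These genes vary together, so the 8 are not separate findings.

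The other 8 were spread over 6 libraries. Wild-type replicate 5 was 7.98 for Mmp13 (9.08 to 9.37 in the others) and 12.71 for Sdhc (12.54 to 12.57). Aass was 14.81 in Falcor-/- replicate 6 (13.90 to 14.10). Foxa2+/- replicate 11 had 13.10 for the clock output gene Dbp (11.30 to 11.48) and 9.06 for Ak4 (8.39 to 8.44), replicate 12 had 5.91 for Rims2 (5.32 to 5.42) and replicate 14 had 6.80 for Svopl (7.58 to 7.64). Kng2 was 9.51 in double-heterozygous replicate 17 (8.24 to 8.26).

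The fall of endothelial genes in Foxa2+/- and in the double-heterozygous label was weighed against technical sources. A smaller share of endothelial cells among the sorted cells was tested on the 200 genes outside all lists that follow the endothelial mean most closely between libraries of the same genotype. Their median change was -1.76 in Foxa2+/- and -2.10 in the double-heterozygous label, so such a smaller share stays open; 0 of the 24 endothelial genes stand in another list, Cdh5 and Cldn5 were at 14.35 and 13.48 in wild type although EpCAM+ capture should remove these cells, and the effect may be one of the sort or of the genotype. A lower epithelial share in wild type stays open, but not with all other cell types raised alike. The endothelial list fell beyond the macrophage list by 1.73 (SE 0.337) in Foxa2+/-. No test here separates fewer endothelial cells in the lung from a purer sort.

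The rise of Falcor RNA in Foxa2+/- and in the double-heterozygous label was weighed next. A larger epithelial share cannot be judged from normalized levels of sorted epithelial cells. Falcor rose beyond 123 alveolar type 2, club, ciliated and junction genes (median 0.0032 in Foxa2+/- and 0.149 in the double-heterozygous label, Epcam 0.10 and 0.30). That the double-heterozygous libraries are Foxa2+/- samples under a wrong label cannot be told apart from a right label. Limma called 370 genes between these genotypes and at most 7 in any other split of the 8 libraries, but Foxa2+/- samples of another day or litter could differ as much, the labels give neither, and the level of Falcor (-0.04, 95% confidence interval -0.68 to 0.60) does not show a lost copy. A rise of Falcor when Foxa2 is lowered, in either label, may be a biological effect, which no test here addressed beyond the change itself (1.52, SE 0.29, adjusted p = 0.00325 in Foxa2+/-).

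Whether other splits of the libraries give as many changed genes was asked for each comparison. The real grouping gave 932 genes in Foxa2+/- and 2254 in the double-heterozygous label against wild type. Of 100 splits run only the real 1 reached these counts, with 71 and 1361 genes in the highest other split. Between the double-heterozygous label and Foxa2+/- it was 1 of 35, the lowest share possible. Chance is unlikely for these, not excluded. In Falcor-/- against wild type (1444) and against Foxa2+/- (2540), 2 of 100 splits reached the count, the highest other with 3393 and 4850. The first of those splits exchanged Falcor-/- replicate 7 and wild-type replicate 5, and the other put Falcor-/- replicate 7 with all 4 Foxa2+/- libraries. Chance stays open for the double-heterozygous label against Falcor-/- (785), where 7 of 100 splits reached the count and the highest gave 3304.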

How the results depend on the processing

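The endothelial mean as a covariate, the endothelial and mesenchymal means together as covariates, and the gene lists with each library left out were chosen only after results were seen. The other alternatives, chosen before the data were examined, recomputed the results with each library left out in turn, equal medians, a further quantile normalization, no filter, a stricter filter, no intensity trend, library weights, a fit of the 2 genotypes alone, and Xist or the mean of the immune lists as a covariate. No paired analysis was possible because the replicate numbers 1 to 18 are all different. A covariate cannot test the list it is made from, so those tests were not run, and no pseudocount alternative was run because the values came as logs. Sequencing depth is unknown, so what it limits cannot be stated, and no result near the floor was tested for counting error.

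With 1 library left out, the change of Foxa2 ran from -0.29 to -0.15 in Falcor-/-, -0.61 to -0.55 in Foxa2+/- and -0.68 to -0.52 in the double-heterozygous label, and that of Falcor from -4.24 to -3.77, 1.39 to 1.65 and 1.35 to 1.61, each on the same side of the threshold. Counts of changed genes ran from 354 to 3926 (Falcor-/- against wild type), 556 to 1118 (Foxa2+/- against wild type), 1342 to 2435 (double-heterozygous label against wild type), 764 to 4742 (Falcor-/- against Foxa2+/-), 90 to 381 (double-heterozygous label against Foxa2+/-) and 412 to 1233 (double-heterozygous label against Falcor-/-). Lists passing ran from 7 to 15, 9 to 15, 14 to 16, 11 to 17, 12 to 15 and 14 to 21 in the same order, and r between fold changes from 0.257 to 0.412, 0.627 to 0.729 and 0.601 to 0.704. Named genes kept direction and call in 877 of these runs and lost the call in 175, and lists kept them in 1551, gained a call in 74 and lost it in 49.

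Counts of changed genes by setting follow, in the order Falcor-/-, Foxa2+/- and double-heterozygous label against wild type, Falcor-/- against Foxa2+/-, double-heterozygous label against Foxa2+/- and against Falcor-/-. A change of at least 1 log2 unit left 286, 468, 781, 608, 148 and 372 by construction, and a false discovery rate of 0.10 gave 3528, 1437, 4516, 789 and 1484 (the double-heterozygous label against wild type stayed within 1.5 times). Library weights gave 3446, 1947, 4939, 4757 and 2125 in the first 5, and brought the change of Foxa2 in Falcor-/- past the threshold (-0.27, adjusted p = 0.0485). A fit of the 2 genotypes alone, with fewer samples, gave 483, 1181 and 342 in the first, the Falcor-/- against Foxa2+/- and the last comparison. Xist as a covariate gave 414 for Falcor-/- against wild type and 350 against Foxa2+/-, and the immune covariate 994 for the double-heterozygous label against wild type and 247 against Falcor-/-. The endothelial covariate gave 157, 0, 2 and 26 in the first 4 and 4 in the last, and both covariates 525, 0, 3, 51 and 5. Where limma called 0, 619 and 663 genes had an unadjusted p under 0.05. The cause was not tested, except that 82.3% of the endothelial mean's variance lies between genotypes, which widens the SE of the genotype differences.

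The endothelial covariate, and both covariates, ended these calls: Foxa2 in Foxa2+/- (-0.96, adjusted p = 0.147, and -0.96, adjusted p = 0.242) and in the double-heterozygous label (-1.09, adjusted p = 0.087, and -1.07, adjusted p = 0.138), and Falcor in Foxa2+/- (2.09, adjusted p = 0.908, and 2.09, adjusted p = 0.845) and in the double-heterozygous label (2.18, adjusted p = 0.645, and 2.16, adjusted p = 0.52). Named genes that turned direction were Sparc in Foxa2+/- (0.13 and 0.14) and, in the double-heterozygous label, Azgp1 (-0.55 and -0.68), Cav1 (0.088 and 0.15), Spock2 (0.32 and 0.33) and, under the endothelial covariate, Col4a3 (0.015). Of all named gene results 14 stayed, 96 lost the call and 5 turned under the endothelial covariate, and 22, 89 and 4 under both. The cause was not tested.

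Lists passing were 0, 0, 0, 0, 1 and 0 with an estimated correlation, which by construction widens the error where members of a list vary together, and fry gave 1, 7 and 9 against wild type and 8 for the double-heterozygous label against Foxa2+/-. Fry also turned the locus list in the double-heterozygous label against Falcor-/- (adjusted p = 0.0104). The endothelial covariate left 3 lists in Foxa2+/- and 7 in the double-heterozygous label against wild type and 7 in Falcor-/- against Foxa2+/-, and both covariates 7 in Falcor-/-, 2, 7 and 7. Lists that turned direction are given with adjusted p under the endothelial covariate and under both. In Foxa2+/- they were alveolar type 1 (0.486 and 0.498), TGF-beta (0.594 and 0.509), lymphocytes (0.73 and 0.695) and, under both only, alveolar type 2 (0.998). In the double-heterozygous label they were alveolar type 1 (0.000667 and 0.00221), Notch (0.562 and 0.384), interferon (0.923 and 0.186), macrophages (0.936 and 0.783), lung transcription factors under the endothelial covariate (0.0495) and lymphocytes under both (0.030). In Falcor-/- TGF-beta turned under both (0.875), and against Foxa2+/- alveolar type 1 (0.993 and 0.982). In the double-heterozygous label against Falcor-/- alveolar type 1 (0.000389 and 0.000471), lung transcription factors (0.489 and 0.439) and, under both, interferon (0.0373) turned. The immune covariate turned the surfactant lipid list in the double-heterozygous label (0.019). The cause was not tested. With split controls r was 0.529 for Falcor-/- and 0.513 for Foxa2+/- against the double-heterozygous label.

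Equal medians, library weights and no filter kept all 115 named gene results, the further quantile normalization 114, no trend 107, the immune covariate 101, Xist 93 and the fit of the 2 genotypes alone 89, each of the others losing the call with its direction kept. The stricter filter left 94 of these genes' results in the test, all with the same direction and call. Equal medians kept all 186 list results in direction and call.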

Other observations

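Tests of genes near Foxa2 on chromosome 2 and the genes named in this part were chosen only after results were seen. The macrophage gene C1qa lay at 13.08 to 13.97 in wild type, 13.17 to 14.10 in Foxa2+/- and 9.58 to 10.49 in the double-heterozygous label. In Falcor-/- replicates 7 and 9 it was 13.15 and 13.73, and in 6, 8 and 10 it was 8.92, 9.78 and 9.83. Mmp9 split likewise (8.60 and 9.17, and 6.27, 6.87 and 6.75). Siglecf and Cd68 did not.

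No list of the circadian genes Dbp, Per3, Tef and Arntl was tested. In the double-heterozygous label Dbp, Per3 and Tef were 1.84, 0.93 and 0.76 above wild type (adjusted p = 0.0236, 0.00543 and 0.000792). Arntl was lower (-1.08, adjusted p = 0.017). In Falcor-/- Dbp did not pass (1.48, adjusted p = 0.0574), but Arntl was 9.15 to 9.91 (wild type 10.09 to 11.47). Per3 and Tef overlapped wild type. The labels give no time of collection.

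Ddx3y is on and Xist low in every library, so all 18 come from male mice.

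Genes changed in the same direction in all 3 mutant genotypes stood near Foxa2 more often than elsewhere. Of the 100 tested genes nearest to it in gene order 5 were among them (Plcb1, Btbd3 and Thbd lower, Bfsp1 and Cst8 higher), against 146 of 14637 elsewhere, or 0.998% (Fisher's exact p = 0.00365), so a variant of another mouse strain carried along with the edited locus stays open and may account for Bfsp1 and Cst8. A short-range effect of the locus is undecided, with 2 of the 20 nearest and 3 of the other 80 (Fisher's exact p = 0.261). Endothelial RNA stays open for Plcb1 and Thbd, which followed the endothelial mean within genotypes (Pearson r 0.868 and 0.961). Btbd3 (r 0.625) changed alike in Falcor-/-, Foxa2+/- and the double-heterozygous label (-0.57, -0.48 and -0.51), unlike that mean. For genes higher in all 3, 2 of 100 stood against 41 of 14637 (Fisher's exact p = 0.0344). The share called near Foxa2 passed in 1 of 6 comparisons, the double-heterozygous label against wild type (25% against 14.9% elsewhere, adjusted p = 0.0338). It did not in Falcor-/- (12% against 9.49%, adjusted p = 0.36) or Foxa2+/- (12% against 6.18%, adjusted p = 0.0636). The pattern was sought after the overlap was known, so its p may be too small.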
